A study of Mus musculus with 28 samples.

How the data were processed

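The series holds bulk libraries of about 2000 sorted cells each, made with an adapted SMART-Seq2 protocol, and a pair of 10x Chromium single-cell libraries. Per the labels, TopHat, RSEM and DESeq were used with the mm9 genome for the bulk libraries, with no role, order or version stated, and Cell Ranger 1.3 with mm10 for the single cells. The deposited bulk count tables hold expected counts (estimated counts of reads per gene, not scaled for depth or length), of which 22.6% in the subset and 30.5% in the treatment table were not whole numbers. The deposited normalized tables hold a signal of unnamed scale that, within a gene, was proportional to the expected counts with 1 factor per library for 100% of the 2789 and 4904 genes checked, within 1%. The deposited single-cell count table holds counts (UMI) for 27933 genes in 5471 cells, and the authors' scaled table holds the natural log of 1 plus UMIs scaled to 1 total per cell, for 15690.0 genes in 5463 cells. The 8 cells absent from the scaled table had at least 11.3% mitochondrial UMIs.

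The count tables held 21614 and 20603 gene names. Of the rows in the subset experiment, 27 had names turned into dates and 4 had a repeated name. The rows with a repeated name were left out, and all others were kept under the names as given. The ribosomal RNA gene Rn45s took 10.7 to 20.7% of the counts of a library. No genome coordinates were used, because the labels name another genome version than the reference at hand. Expected counts were rounded to whole numbers. Groups followed the labels, with 14 libraries in the subset and 12 in the treatment experiment. The numbers in the titles, descriptions and names of the libraries were checked for pairing across groups, and no block was used in the main models. By title number, all 3 pairs of a DN isotype with a DN blockade library deviated together from their group means (correlations of 0.122 to 0.383). The labels give no reason for it, so this pairing is not established.

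Each experiment was fitted with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood test, group means without a block), on 12388 genes in the subset and 12710.0 in the treatment experiment, with a biological coefficient of variation of 0.624 and 0.229. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. In simulated data with 200 changed genes at the depth and spread of these libraries, the test called 19 to 70% of genes changed 2-fold and 60 to 95% of genes changed 4-fold, depending on the comparison. Gene lists were tested with camera (limma 3.58.1) with the preset correlation of 0.01, with an estimated correlation and with fry, where at least 5 members were measured, and adjusted over the lists of a comparison. The 23 lists held naive and homing, memory precursor, cytotoxic, terminal effector, co-inhibitory, S phase, G2/M, glycolysis, oxidative phosphorylation, interferon-stimulated, immediate early, residency, cytokine receptor, chemokine receptor, heat shock and antigen presentation genes. They also held markers of myeloid, B, CD4 T, natural killer and gamma-delta T, tumour or stroma, blood and core T cells. Gene sets of the subsets held at most 150 genes that passed the test and were at least 1 log2 unit higher in 1 subset than in the other 2.

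Genes were named by a rule fixed before the data were examined, as were the comparisons, tests, lists and most alternatives. It took the genes of the sort, the 8 genes higher and the 8 lower with the smallest p among called genes whose groups did not overlap, up to 4 called members of each list, and 14 genes of T cell states in every comparison; where no gene was called, it took the 3 smallest p each way. Other genes are said to have been chosen after their values were seen. The results of some genes that the rule took are not reported here. A count of 0 in a group was given the limit of 3 counts over the group's total. Limits and intervals cover counting error only.

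Single cells were kept with at least 500 genes and at most 10% mitochondrial UMIs, which removed 8 isotype and 6 blockade cells for few genes and 8 isotype cells for mitochondrial UMIs, some of them for both. UMIs were summed over the cells of a library and given as CPM with exact Poisson intervals, and shares of cells with exact binomial (Clopper-Pearson) intervals at 95%. Clustering used scanpy 1.11.5 with 2000 variable genes, 30 principal components, 15 neighbours and Leiden (igraph 0.11.9) at a resolution of 1.0, over both libraries without the library as a factor. Clusters were named from marker lists. Median log2 ratios of lists were ranked among 10000 random lists matched on expression in 20 bins. On simulated lists of 25 genes changed 1.5-fold, 92% passed percentile 97.5, and of unchanged lists 5% fell outside. The simulated genes varied independently, so these rates do not hold for lists whose genes vary together. A doublet caller marked 2 cells (0.0367%), so it had not worked and no doublets were removed. No test between the single-cell libraries was made, since each treatment had 1 library.

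The alternatives were DESeq2 1.42.0 size factors, the DESeq2 test, limma-voom, limma-trend on the authors' normalized values with a pseudocount of 1, no filter, a filter of 10 counts, only the compared groups, a threshold of 1 log2 unit, each library left out in turn, blocks by the numbers of the libraries, sets of at most 50 and 400 genes, sets without cell cycle genes, and Leiden resolutions of 0.5 and 1.5. For single cells, all cells, T cell clusters alone, median-of-ratios scaling and thinning to 1000 UMIs were also used. Some alternatives were added after the data had been seen. These left out 3 memory-like and naive-like libraries that stood apart in their groups, or left out Rn45s. Blocks by pools of name numbers and in DN libraries alone, and the SK block for gene sets, were also added then. Other splits of the libraries into groups of the same size were fitted, at most 100 per comparison. Analyses used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.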

Results

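RNA was sequenced from CD8+ tumour-infiltrating lymphocytes (TILs) of wild-type C57BL/6 mice that carried MC38-OVA tumours, a colon carcinoma line that expresses ovalbumin. In the subset experiment, PD-1-CD8+ TILs were sorted into memory-like cells (CD62L-Slamf7hiCX3CR1-, n = 5), effector-like cells (CD62L-Slamf7hiCX3CR1+, n = 3) and naive-like cells (CD62LhiSlamf7-CX3CR1-, n = 6). The names of effector-like replicates 1 and 2 carry 3 numbers each (1, 2 and 3, and 4, 5 and 6) and that of replicate 3 carries 5, so these libraries may be pools and may share an animal, and whether they are independent is not known. In the treatment experiment, Tim-3-PD-1- (DN) and Tim-3+PD-1+ (DP) cells were sorted after isotype control antibodies or after blockade with antibodies to Tim-3 and PD-1, with 3 libraries in each of the 4 groups. Single cells were sequenced from 1 library of DN cells after isotype and 1 after blockade. The libraries held 5027523 to 6786375 counts in effector-like, 5474899 to 6527589 in memory-like and 6689348 to 7978932 in naive-like cells. They held 8850713 to 9895277 counts in DN isotype, 8005818 to 9958960 in DN blockade, 9526249 to 12037446 in DP isotype and 10875486 to 13579262 in DP blockade cells. Expression is given as counts-per-million (CPM), mean ± SD over the libraries of a group, and differences as log2 fold changes ± SE. The p-values measure only the spread between these samples.

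The comparison of effector-like with memory-like cells asked what separates the CX3CR1+ and CX3CR1- fractions of Slamf7hi PD-1- TILs. Effector-like cells held less mRNA of naive and homing genes and of memory precursor genes, and more of genes of cytotoxicity and terminal effector differentiation. Of 20 naive and homing genes, 9 were lower and 11 did not pass (14 lower and 2 higher when adjusted over the list alone). Ccr7, the receptor for lymph node chemokines, differed by -2.57 ± 0.36 (adjusted p = 0.000915), and Myc, a growth regulator, by -2.57 ± 0.21. Of 19 memory precursor genes, 9 were lower and 10 did not pass (11 lower when adjusted over the list alone). Tcf7, which encodes the transcription factor TCF-1 of naive and memory T cells, differed by -1.60 ± 0.16 (adjusted p = 8.42e-05). Id3 differed by -2.26 ± 0.41 and Il7r, the interleukin-7 receptor, by -1.06 ± 0.24 (adjusted p = 0.0302). Cxcr5 had 0 counts in the effector-like libraries, which allows up to 0.171 CPM, and 30.1 ± 15.4 CPM in memory-like cells, at least 176-fold higher. Lef1, a partner of TCF-1, was at 108 ± 17.6 and 130 ± 24.1 CPM and did not pass (adjusted p = 0.740).

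Of 23 cytotoxic genes, 4 were higher in effector-like than in memory-like cells and 19 did not pass (7 higher and 2 lower when adjusted over the list alone). Gzma, a granzyme, reached 1403 ± 121 CPM against 202 ± 46.9 (log2 2.80 ± 0.32, adjusted p = 0.000186), and the chemokine gene Ccl5 reached 4905 ± 476 against 1422 ± 193. Prf1, the pore-forming perforin, was at 263 ± 86.2 against 107 ± 40.3 CPM (adjusted p = 0.0463) and Fasl differed by 1.38 ± 0.33 (adjusted p = 0.0412). Gzmb was at 3145 ± 1032 against 1430.3 ± 743 CPM and did not pass (adjusted p = 0.323). Of 25 terminal effector genes, 4 were higher and 21 did not pass (10 higher when adjusted over the list alone). Among them, Cx3cr1, the sorted fractalkine receptor, differed by 4.60 ± 0.78 and Klrg1, a marker of terminal effectors, by 3.60 ± 0.63 (adjusted p = 0.00583). Memory-like cells held more Plac8, at 540.3 ± 95.4 against 161 ± 16.3 CPM, and more Ikzf2, at 81.3 ± 11.8 against 9.74 ± 3.26 CPM. Klra6 and Klra7, which encode natural killer cell receptors and belong to a family with near-identical copies whose reads are hard to tell apart, were at 129 ± 23.4 and 214 ± 38.9 CPM in memory-like cells against 1.09 ± 1.89 and 17.4 ± 13.0 CPM. Genes of plasmacytoid dendritic cells, a list chosen after its values were seen in the treatment experiment, were higher in memory-like cells for 19 of 20 (median log2 ratio 2.85), with Siglech at 186 ± 193 against 6.41 ± 8.13 CPM. Markers of tumour and stroma differed between libraries of the same group, with a mean log2 CPM of 4.59 and 4.65 in effector-like replicates 1 and 2 and 0.27 in replicate 3. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 237 of 12388 genes, 60 higher and 177 lower in effector-like cells. The count was 105 without effector-like replicate 2, 153 without effector-like replicate 1 and 156 without memory-like replicate 3. In camera, the adjusted p with an estimated correlation was 0.000517 for naive and homing genes, 0.000409 for memory precursor genes, 0.0136 for cytotoxic genes and 0.000665 for terminal effector genes.

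**Figure D1:**
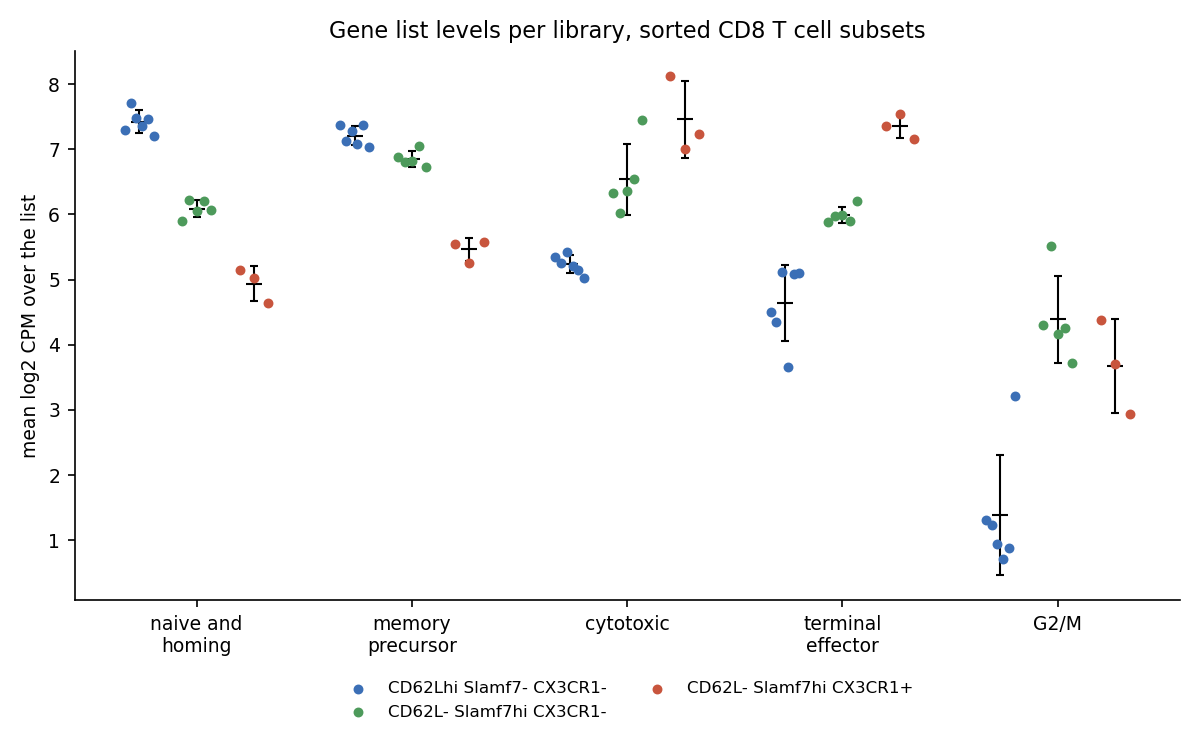
Mean log2 CPM of 5 gene lists in each library of the sorted PD-1- subsets, with the mean and SD of each group. Naive and homing genes lay between 7.21 and 7.71 in naive-like, 5.90 and 6.22 in memory-like, and 4.64 and 5.15 in effector-like libraries, and terminal effector genes in the opposite order.

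The comparison of effector-like with naive-like cells spanned the extremes of the PD-1- sort. Effector-like cells held less of nearly the whole naive and homing list and more of most cytotoxic and terminal effector genes. Of the 20 naive and homing genes, 18 were lower and 2 did not pass (18 lower when adjusted over the list alone), with Tcf7 at 99.4 ± 20.1 against 725 ± 73.9 CPM (log2 -2.87 ± 0.17, adjusted p = 9.37e-08). Lef1 differed by -1.78 ± 0.23 and Ccr7 by -3.99 ± 0.38. Of the memory precursor genes, 12 were lower; Bach2, a repressor of effector differentiation, differed by -2.50 ± 0.30 and Id3 by -3.22 ± 0.43. Of 23 cytotoxic genes, 17 were higher (19 when adjusted over the list alone), with Gzmb at 3145 ± 1032 against 193 ± 127 CPM (log2 4.03 ± 0.45, adjusted p = 3.38e-05). Gzma differed by 5.26 ± 0.33, Prf1 by 2.19 ± 0.30 and Ifng, the interferon gamma gene, by 2.35 ± 0.37. Of 25 terminal effector genes, 15 were higher (20 when adjusted over the list alone); Klrg1 was at 144 ± 43.1 against 0.521 ± 0.830 CPM. Tbx21, which encodes the effector transcription factor T-bet, differed by 1.37 ± 0.25 (adjusted p = 0.00331), Bhlhe40 by 2.23 ± 0.23 and Prdm1, which encodes Blimp-1, by 2.87 ± 0.49. Of the co-inhibitory list, 10 genes were higher and 2 lower, with an adjusted p = 0.296 with an estimated correlation. Rpsa, a ribosomal protein gene of a family with many near-identical copies, differed by -1.34 ± 0.08 and the elongation factor gene Eef1a1 by -1.04 ± 0.07. All 25 genes of the G2/M list were higher and 5 passed, among them Kif11 and Birc5 (adjusted p = 0.187 for the list with an estimated correlation).

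The names of the naive-like libraries carry another date than those of the other subsets, so date and group cannot be told apart in either comparison with naive-like cells. The share of Rn45s, a ribosomal RNA gene, also moved with the groups, at 17.8 to 20.7% of the counts in naive-like, 12.6 to 17.4% in memory-like and 10.7 to 14.1% in effector-like libraries, and 11524 to 14355, 12980.0 to 16045 and 13511 to 15035 genes were detected. edgeR called 795 genes between effector-like and naive-like cells, 325 higher and 470 lower. The count was 484 without effector-like replicate 1 and 517 without effector-like replicate 2. It was 1319 without memory-like 2, naive-like 4 and naive-like 6, which stood apart in their own groups. In camera with an estimated correlation, the adjusted p was 2.94e-05 for naive and homing, 0.000141 for memory precursor, 0.000181 for cytotoxic and 2.03e-05 for terminal effector genes.

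Memory-like cells, compared with naive-like cells to ask how far they had moved from the naive state, held less mRNA of naive and homing genes and more of cytotoxic and cell cycle genes. Of the 20 naive and homing genes, 14 were lower (19 when adjusted over the list alone), with S1pr1, the receptor for egress from lymphoid tissue, at 161 ± 25.9 against 478 ± 90.1 CPM (log2 -1.57 ± 0.17, adjusted p = 0.00022). Tcf7 differed by -1.27 ± 0.13 and Lef1 by -1.52 ± 0.18. The memory precursor list had a mean log2 CPM of 6.72 to 7.05 in memory-like and 7.03 to 7.37 in naive-like libraries. It was therefore not highest in memory-like cells. Of the cytotoxic genes, 13 were higher (18 when adjusted over the list alone); Gzma differed by 2.46 ± 0.28, Gzmb by 2.89 ± 0.41, Gzmk by 3.15 ± 0.42 and the chemokine gene Ccl4 by 2.26 ± 0.28. Of the terminal effector genes, 10 were higher (12 when adjusted over the list alone), with Klrc1 at 184 ± 20.95 against 54.1 ± 17.1 CPM. Of the G2/M genes, 11 were higher (18 when adjusted over the list alone), with Mki67, a proliferation marker, at 60.3 ± 18.4 against 4.03 ± 3.29 CPM (log2 3.88 ± 0.62, adjusted p = 0.00241). Of 26 S phase genes, 4 were higher, with Tyms, the thymidylate synthase gene, at 2.32 ± 0.26. Of 16 chemokine receptor genes, 7 were higher and 1 lower; Cxcr6 differed by 2.29 ± 0.35 and Ccr7 by -1.42 ± 0.27. Lag3, a co-inhibitory receptor, was at 86.8 ± 23.1 against 12.3 ± 12.0 CPM (adjusted p = 0.0159), and Irf1 was at 651 ± 85.1 against 1599 ± 205 CPM. The regulatory T cell gene Foxp3, at 6.56 ± 8.27 against 0.0522 ± 0.0810 CPM, was among 4 of 7 CD4 T cell markers that were higher. The share of Rn45s was 12.6 to 17.4% in memory-like and 17.8 to 20.7% in naive-like libraries. Of 20 genes of plasmacytoid dendritic cells, 20 were higher in memory-like cells (median log2 ratio 2.47), with Siglech at 186 ± 193 against 26.2 ± 24.2 CPM. The macrophage gene C1qb was at 0.0368 ± 0.0823 against 24.2 ± 29.97 CPM, with an SD above its mean in naive-like cells. edgeR called 683 genes, 345 higher and 338 lower in memory-like cells. The count was 340.0 without memory-like replicate 1 and 429 without memory-like replicate 3. With an estimated correlation, the adjusted p in camera was 0.00031 for naive and homing, 0.00141 for cytotoxic, 0.00031 for terminal effector, 0.0282 for G2/M, 0.0249 for S phase, 0.0409 for chemokine receptor and 0.0282 for CD4 T cell genes. It was 0.0626 for the co-inhibitory list, 0.138 for oxidative phosphorylation and 0.262 for interferon-stimulated genes, which the preset correlation called.

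In DN cells, the comparison of blockade with isotype asked whether TILs sorted as negative for Tim-3 and PD-1 change when these receptors are blocked. Genes of effector function rose and genes of naive cells fell. Of 23 cytotoxic genes, 3 rose and 20 did not pass (11 higher when adjusted over the list alone): Prf1, from 41.1 ± 11.5 to 107 ± 22.2 CPM (log2 1.38 ± 0.23, adjusted p = 0.0231), Ifng, from 18.6 ± 1.94 to 42.9 ± 12.5 CPM (adjusted p = 0.0286), and Gzmk (log2 0.77 ± 0.15, adjusted p = 0.0334). Of 25 terminal effector genes, 3 rose and 22 did not pass (12 higher and 1 lower when adjusted over the list alone). They were Tbx21, from 83.3 ± 15.6 to 167 ± 26.8 CPM (adjusted p = 0.0145), and the receptor genes Klrc1 (log2 0.98 ± 0.15) and Klrk1 (log2 0.99 ± 0.19). Of 20 naive and homing genes, 5 fell and 15 did not pass (15 lower when adjusted over the list alone). Lef1 fell from 268 ± 40.6 to 103 ± 36.3 CPM (log2 -1.38 ± 0.21, adjusted p = 0.0173), Ccr7 from 857 ± 227 to 283 ± 133 CPM (adjusted p = 0.0415), and Myc and Foxp1 by 0.86 and 0.74 on the log2 scale. Bcl2, a survival gene of the memory precursor list, fell by 1.14 ± 0.20 (adjusted p = 0.0258). Of 30 co-inhibitory genes, 6 rose (12 higher and 1 lower when adjusted over the list alone), with an adjusted p = 0.172 with an estimated correlation. They included Havcr2, the gene of Tim-3 itself, from 3.91 ± 2.10 to 25.4 ± 9.76 CPM (log2 2.72 ± 0.34, adjusted p = 0.00713). Pdcd1, the gene of PD-1, rose from 33.2 ± 7.53 to 107 ± 42.3 CPM (adjusted p = 0.0166). Cxcr6, a chemokine receptor gene that is also on this list, rose by 1.40 ± 0.28 on the log2 scale. Itga1, an integrin of tissue-resident T cells, rose by 1.84 ± 0.31 and Ccr2 by 1.08 ± 0.19. Tcf7 was at 413 ± 78.1 and 244 ± 73.3 CPM (adjusted p = 0.0877), Gzmb at 295 ± 32.8 and 561 ± 214 CPM (adjusted p = 0.0700), and Il7r at 399 ± 58.8 and 253 ± 20.4 CPM (adjusted p = 0.0582), and these did not pass. Lag3, at 150.1 ± 24.3 and 149.9 ± 32.8 CPM, and Mki67, at 42.2 ± 11.3 and 42.7 ± 3.38 CPM, were level within the spread between libraries.

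In camera, 13 of 23 lists were called in DN cells with the preset correlation, and 4 of these held with an estimated correlation. These were cytotoxic genes (adjusted p = 0.0145), terminal effector genes (adjusted p = 0.0145), naive and homing genes (adjusted p = 0.0493) and blood genes (adjusted p = 0.00146). With an estimated correlation the adjusted p was 0.172 for co-inhibitory, 0.306 for immediate early, 0.367 for chemokine receptor, 0.515 for myeloid, 0.561 for CD4 T cell, 0.617 for natural killer and gamma-delta T cell and 0.645 for B cell genes. It was 0.388 for memory precursor, glycolysis and residency genes, 0.724 for interferon-stimulated, 0.768 for S phase, G2/M, cytokine receptor and tumour or stroma, 0.801 for antigen presentation and 0.940 for oxidative phosphorylation, heat shock and core T cell genes. edgeR called 142 of 12710 genes, 66 higher and 76 lower under blockade, and 2, the red cell genes Alas2 and Hba-a2, when only these 6 libraries were fitted without the spread of the DP libraries. The count was 22 without DN isotype replicate 1, 28 without DN isotype replicate 2, 229 without DN isotype replicate 3, 82 without DN blockade replicate 1 and 42 without DN blockade replicate 3. The 3 pairs of a DN isotype with a DN blockade library deviated together by title number. This match was found in the same data, so pairing by the title number is not established. With this number as a block in all libraries 59 genes were called, and 25 of the 35 named genes called without it, with Ifng at an adjusted p = 0.0564, Bcl2 and Ccr2 at 0.0520, Gzmk at 0.0604, Klrk1 at 0.0623, Foxp1 at 0.0677 and Cxcr6 at 0.0678. With the block in DN libraries alone 529 genes were called, among them all 35 and also Tcf7 (adjusted p = 0.0139), Gzmb (0.0246) and Il7r (0.0252). With an estimated correlation and either block, the same 4 lists passed. The DN blockade libraries held 15705 to 16162 detected genes against 15037 to 15581 under isotype, and 17.7 to 18.8% against 12.6 to 18.1% of Rn45s.

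**Figure D2:**
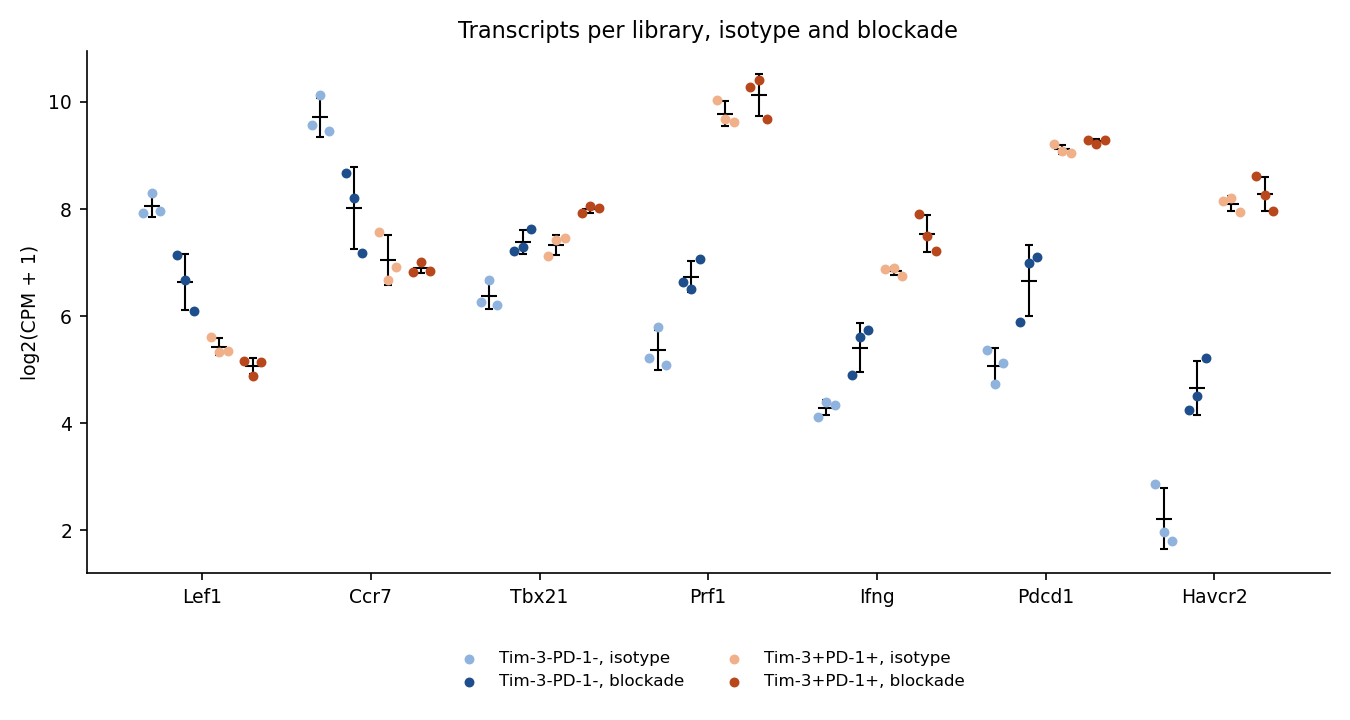
Expression of 7 genes in the libraries of the treatment experiment as log2(CPM + 1), with the mean and SD of each of the 4 groups. In DN cells Lef1 and Ccr7 lay lower and Tbx21, Prf1, Ifng, Pdcd1 and Havcr2 higher after blockade.

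Transcripts of other cell types moved with the DN groups beside these genes. Of 6 blood genes measured, 5 fell; Alas2, the haem synthesis enzyme of red cell precursors, went from 94.7 ± 27.8 to 0.445 ± 0.412 CPM (adjusted p = 1.76e-05) and Hbb-b2, a haemoglobin gene, from 161 ± 62.5 to 1.11 ± 1.93 CPM. Hba-a2 had 0 counts in the blockade libraries, which allows up to 0.108 CPM, against 104.5 ± 43.1 CPM, so it was at least 968-fold lower. Haemoglobin genes have near-identical copies, so the split between them is uncertain. Of 24 myeloid genes, 3 rose (9 higher and 1 lower when adjusted over the list alone): Lyz2, a lysozyme gene with the near-identical copy Lyz1, went from 2.63 ± 1.02 to 49.4 ± 37.5 CPM (adjusted p = 0.0128), and Fcgr1 from 0 counts, which allows up to 0.106 CPM, to 6.59 ± 4.0 CPM. Siglech, a gene of plasmacytoid dendritic cells that was chosen after its values were seen, was at 581 ± 134 CPM in DN isotype, 273 ± 77.6 in DN blockade, 3.59 ± 3.59 in DP isotype and 0.455 ± 0.502 in DP blockade cells.

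**Figure D3:**
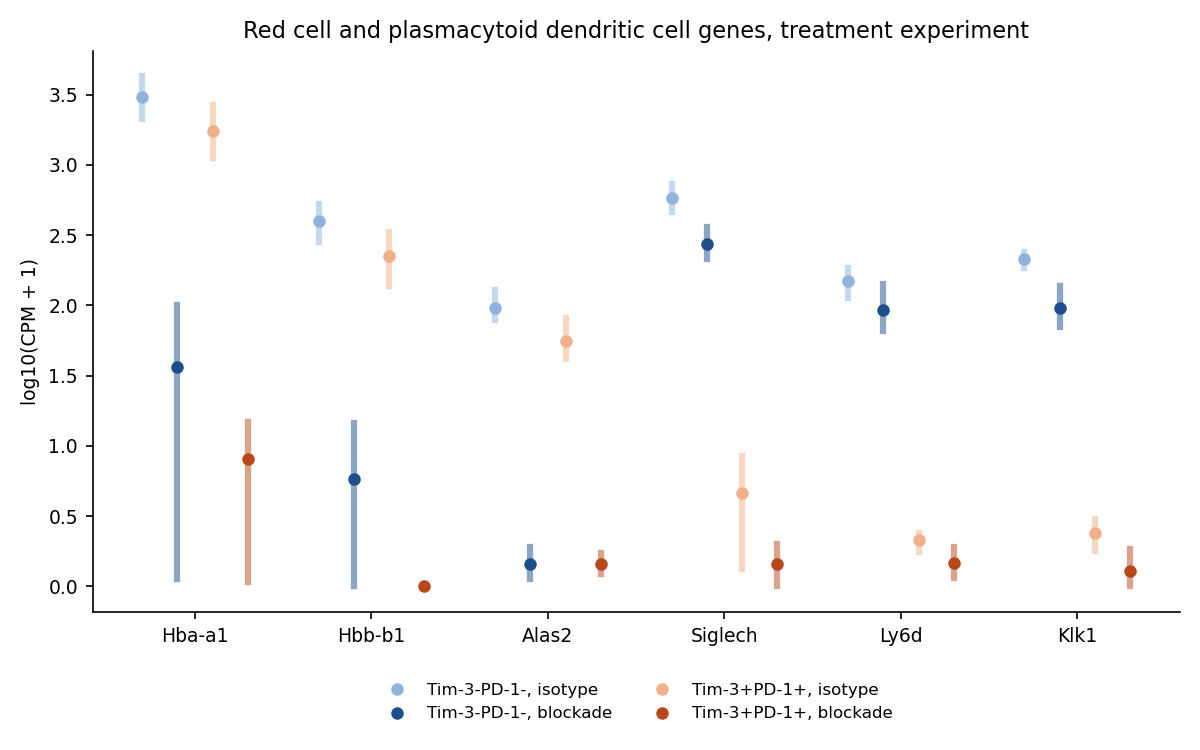
Levels of 3 erythrocyte genes and 3 plasmacytoid dendritic cell genes, chosen after their values were seen, in the 4 groups of the treatment experiment as log10(CPM + 1); points are means and bars run from the lowest to the highest library. Alas2 was at 94.7 CPM in DN isotype and 0.445 CPM in DN blockade libraries, and Siglech at 581 and 273 CPM.

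In DP cells, the same comparison asked whether TILs that carry both receptors change under blockade. Dnajb11, a chaperone of the endoplasmic reticulum, rose from 83.3 ± 7.36 to 149 ± 10.8 CPM (log2 0.84 ± 0.13, adjusted p = 0.0343), and Pdcd4, a translation inhibitor, fell from 157 ± 19.1 to 81.7 ± 14.5 CPM (log2 -0.94 ± 0.14, adjusted p = 0.0343). The other 6 genes called were lower. Among them were the red cell genes Alas2, Hbb-b1, Hbb-b2 and Hba-a2, and Apol11b; Alas2 went from 55.1 ± 21.97 to 0.454 ± 0.262 CPM and Hbb-b2 from 109.8 ± 34.6 to 0.0509 ± 0.0882 CPM. Of the cytotoxic and co-inhibitory genes, 0 passed (3 and 4 higher when adjusted over the list alone), with an adjusted p = 0.105 and 0.299 with an estimated correlation. Tbx21 was at 161 ± 19.97 and 254 ± 11.9 CPM (adjusted p = 0.246), Lag3 at 392 ± 5.63 and 625.1 ± 98.9 CPM (adjusted p = 0.314), Havcr2 at 274 ± 25.6 and 316 ± 71.4 CPM (adjusted p = 0.939) and Lef1 at 42.3 ± 4.86 and 32.6 ± 3.54 CPM (adjusted p = 0.788). edgeR called 8 genes, 1 higher and 7 lower, beside 909 with an unadjusted p under 0.05; DESeq2 called 55 and limma-voom 1. The count was 3 without DP isotype replicate 1, 4 without DP isotype replicate 3, 5 without DP blockade replicate 1 and 5 without DP blockade replicate 2, and 16 when only these 6 libraries were fitted. Dnajb11 was not called once any 1 of the 6 libraries was left out, and Pdcd4 only without DP blockade replicate 3, whereas Alas2, Hba-a2 and Hbb-b2 were called without each of them.

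Whether blockade acted differently on DN and DP cells was tested as the difference of both effects. No single gene passed in edgeR (0 genes, smallest adjusted p = 0.152), beside 1070.0 genes with an unadjusted p under 0.05 and 98 called by DESeq2. Among the genes with the smallest p-values were Cd4 (difference 2.69 ± 0.42) and Dusp10 (1.33 ± 0.21), each with an adjusted p = 0.152, and, with a negative difference, Havcr2 (-2.51 ± 0.43, adjusted p = 0.192). Tbx21 differed by -0.34 ± 0.21 (adjusted p = 0.699) and Lef1 by 1.01 ± 0.30 (adjusted p = 0.339). Of the naive and homing genes, 0 passed and 11 were higher when adjusted over the list alone, with an adjusted p = 0.266 with an estimated correlation. With the SK number in the descriptions of the libraries as a block, for which pairing stays open, 1 gene passed, Hbb-b1, and with the title number as a block in DN libraries 28 passed. Leaving out DN blockade replicate 1 gave 1 gene, Pdcd1, and leaving out DN blockade replicate 3 gave 3, the myeloid genes Fcgr1 and Lyz2 and the complement gene C3, which was named after its value was seen.

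Gene sets taken from the subset experiment were used to place the treated cells along the sorted subsets. The effector set (23 genes), the memory set (6 genes) and the naive set (58 genes) held genes that were called and at least 1 log2 unit higher in 1 subset than in both others; they were derived from other libraries than those of the treatment experiment. In DN cells under blockade, 18 of 22 measured effector set genes were higher and 3 passed, with a median log2 change of 0.49 (adjusted p = 0.00339 in camera with an estimated correlation). Of the naive set, 55 genes were lower and 10 passed (37 when adjusted over the list alone), with a median of -0.69 (adjusted p = 0.0208). The memory set, which held Plac8, Ly6d, Ncf1, Xcl1 and Ccr9 among others, had a median of -0.70 and an adjusted p = 0.0867 with an estimated correlation (0.0220 with the title number as a block, and 0.0314 with that block in DN libraries alone). Ly6d and Ccr9 are also on the list of plasmacytoid dendritic cell genes, which was higher in memory-like than in naive-like (median 2.47) and effector-like cells (2.85), so this set does not stand for memory T cells alone. The naive set rests only on comparisons with naive-like libraries, whose names carry another date. Subset and date cannot be told apart in this set, which also holds the macrophage gene C1qb. In DP cells the adjusted p was 0.575 for the effector set and 0.899 for the naive set. The effect of blockade differed between DP and DN cells for the effector set (median difference -0.36, adjusted p = 0.0291) and the naive set (median difference 0.65, adjusted p = 0.0299), and for the memory set the adjusted p was 0.150. With the SK number of the libraries as a block and an estimated correlation, the adjusted p of the effector and naive sets was 0.0753 and neither difference passed.

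DP and DN cells were compared within each treatment to show how the populations differ at baseline and under blockade. Under isotype, DP cells held more mRNA of cytotoxic and co-inhibitory genes and less of naive and homing genes. Of 30 co-inhibitory genes, 19 were higher, among them the sorted Havcr2 (log2 6.15 ± 0.36) and Pdcd1 (4.06 ± 0.28), Tnfrsf9, the co-stimulatory receptor 4-1BB (3.82 ± 0.26), Lag3 (1.39 ± 0.16) and Entpd1, which encodes CD39 (2.56 ± 0.18). Of 23 cytotoxic genes, 18 were higher and 1 lower, with Prf1 at 888 ± 144 against 41.1 ± 11.5 CPM (adjusted p = 5.12e-07) and Gzmb at 2056 ± 125 against 295 ± 32.8 CPM. Of the terminal effector genes, 15 were higher and 4 lower; Klrg1 was at 18.9 ± 10.6 and 12.7 ± 2.52 CPM and did not pass (adjusted p = 0.502). Of the S phase genes 24 of 26 and of the G2/M genes 24 of 25 were higher, with Mki67 at 191 ± 16.4 against 42.2 ± 11.3 CPM; with an estimated correlation the adjusted p was 0.0918 and 0.172. Of the naive and homing genes, 19 of 20 were lower, with Tcf7 at 25.6 ± 3.0 against 413 ± 78.1 CPM and Lef1 at 42.3 ± 4.86 against 268 ± 40.6 CPM. Id3 differed by -3.45 ± 0.24 and Bcl2 by -2.62 ± 0.21, among 10 lower and 1 higher of the memory precursor genes (adjusted p = 0.0918 with an estimated correlation). Of 17 glycolysis genes, 14 were higher, with the glucose transporter gene Slc2a3 at 2.07 ± 0.18 (adjusted p = 0.172 for the list with an estimated correlation). Markers of other cells differed too: Cd4 was at 2.40 ± 1.20 against 134 ± 12.2 CPM, the B cell gene Cd79b at 1.43 ± 0.328 against 15.1 ± 1.14 CPM, Tyrobp at 29.9 ± 3.23 against 251 ± 43.7 CPM and Lyz2 at 119 ± 15.01 against 2.63 ± 1.02 CPM. edgeR called 3794 genes, 1909 higher and 1885 lower in DP cells. In camera with an estimated correlation the adjusted p was 0.0205 for naive and homing, 0.0142 for cytotoxic, 0.0401 for terminal effector, 0.0401 for co-inhibitory and 0.0401 for natural killer and gamma-delta T cell genes.

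Under blockade, DP cells held more mRNA of co-inhibitory, cytotoxic and S phase genes than DN cells and less of naive and homing genes. Of the co-inhibitory genes, 22 of 30 were higher, with Lag3 at 625.1 ± 98.9 against 149.9 ± 32.8 CPM (log2 2.06 ± 0.17, adjusted p = 6.26e-06) and Tox, a regulator of exhausted T cells, at 73.0 ± 16.6 against 21.8 ± 1.25 CPM (adjusted p = 0.000257). Of the cytotoxic genes, 15 were higher and 2 lower; Prf1 differed by 3.41 ± 0.24 and the chemokine gene Ccl3 by 3.46 ± 0.27. Of 26 S phase genes, 25 were higher, among them the replication helicase genes Mcm5 (1.99 ± 0.12) and Mcm7 (1.55 ± 0.11). Of the naive and homing genes, 18 were lower (19 when adjusted over the list alone); Tcf7 differed by -3.67 ± 0.23 and Lef1 by -1.66 ± 0.22. Of the interferon-stimulated genes, 11 were lower, with Bst2 at 139 ± 34.3 against 302 ± 40.3 CPM (adjusted p = 0.527 for the list with an estimated correlation). Ly6d and Bcl11a, expressed in plasmacytoid dendritic cells and B cells, were at 0.481 ± 0.392 and 0.360 ± 0.116 CPM against 92.1 ± 42.5 and 38.5 ± 7.10 CPM. Rn45s took 11.4 to 15.04% of the counts in DP blockade and 17.7 to 18.8% in DN blockade libraries. edgeR called 3426 genes, 1836 higher and 1590.0 lower in DP cells. With an estimated correlation the adjusted p in camera was 0.0335 for naive and homing, co-inhibitory, S phase and natural killer and gamma-delta T cell genes, 0.0237 for cytotoxic genes and 0.127 for terminal effector genes.

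Single DN cells were compared to show how the effect of blockade is spread over cells. The isotype library held 2950.0 cells and the blockade library 2502 cells after filtering, with a median of 3652 and 3839.5 unique molecular identifiers (UMIs) per cell. Cells carry a suffix that was taken to follow the order of the samples, which the files do not state. With 1 library for each treatment no test was made, and the 95% exact intervals cover counting error only. As CPM of all UMIs of a library, Gzmb was at 275 [265 to 284] in isotype and 1348 in blockade cells, a log2 ratio of 2.30 [2.24 to 2.35]. Gzma was at 120.4 and 570.3 (log2 2.24), Ifng at 104 and 239 (1.20), Tbx21 at 12.6 and 27.3 (1.12), Pdcd1 at 11.7 and 62.0 (2.41) and Lag3 at 20.9 and 81.8 (1.97). Havcr2 was at 1.78 and 13.7 [interval of the log2 ratio 2.30 to 3.66]. Tcf7 was at 237 and 158 (-0.58), Lef1 at 215 and 105 (-1.04) and Il7r at 187 and 118 (-0.66). Prf1 had 49 and 65 UMIs in all, and its interval of -0.15 to 0.97 included 0 and ended below the bulk estimate of 1.38 ± 0.23. The median log2 ratio of 6958 genes with at least 200 UMIs was 0.16, so that ratios near this value show no difference. In bulk DN libraries Lag3 was level (log2 0.00 ± 0.16) and the change of Gzma was not determined (0.33 ± 0.45, with 96.2 ± 70.3 against 76.4 ± 8.86 CPM). Eomes, at 34.9 and 23.4 CPM of UMIs, had the opposite sign in bulk (0.47 ± 0.25, adjusted p = 0.394).

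Clustering gave 14 clusters, and 7 were named by marker lists. The naive-like cluster, with Igfbp4, Ccr7 and Lef1 among its top genes, held 670.0 isotype cells (22.7% [21.2 to 24.3]) and 14 blockade cells (0.560% [0.306 to 0.937]). The effector-like cluster, with Gzma, Ccl5 and Gzmk, held 11.3% [10.2 to 12.5] of isotype and 18.4% [16.9 to 20.001] of blockade cells. The interferon-response cluster, with Ifit1, Ifit3 and Isg15, held 2.17% [1.67 to 2.76] and 10.4% [9.22 to 11.7], and the cycling cluster, with Stmn1 and Birc5, 2.98% [2.40 to 3.66] and 4.52% [3.74 to 5.40]. These shares depend on the resolution: at 0.5 the naive-like share was 41.1% and 1.44%, the effector-like 14.2% and 25.98%, the interferon-response 4.81% and 30.1% and the cycling 2.68% [2.13 to 3.33] and 3.16% [2.51 to 3.92], with intervals that overlap. At 1.5 the naive-like share was 20.5% and 0.360%, and the effector-like 6.64% and 12.3%. Among unnamed clusters, 1 with Ifitm1 and Cxcr6 held 2.54% and 19.9%, and 1 with Dapl1 and Igfbp4 held 16.5% and 0.679%; clusters that come mostly from 1 library may reflect that library. Both clusters named myeloid-like differed in content. That with Lyz2, C1qb and Fcgr1 among its top genes held 0.0678% [0.00821 to 0.245] of isotype and 1.68% [1.21 to 2.26] of blockade cells, and that with Cd74, Ly6d and Klk1, the latter pair on the plasmacytoid dendritic cell list, held 0.508% [0.285 to 0.837] and 0.839% [0.520 to 1.28], while the tumour or stroma-like cluster 1.05% and 1.12%.

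Across lists, 25 of 25 terminal effector genes had a higher UMI CPM in blockade cells (median log2 ratio 1.12), as had 20 of 21 cytotoxic genes (0.89), 28 of 30 co-inhibitory genes (1.02) and 30 of 30 interferon-stimulated genes (1.58). In bulk DN libraries, 24 of 31 interferon-stimulated genes were higher and 0 passed. Of 20 naive and homing genes, 1 was higher (median -0.71). Among the medians of 10000 random lists with like expression, these stood at percentile 100 for the lists that were higher and 0 for naive and homing genes. The percentiles do not allow for correlation between the genes of a list. Of 59 measured genes that bulk DN cells had gained under blockade, 58 had more UMIs in blockade cells (median 1.36), and of 68 that they had lost, 14 had more (median -0.34).

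**Figure D4:**
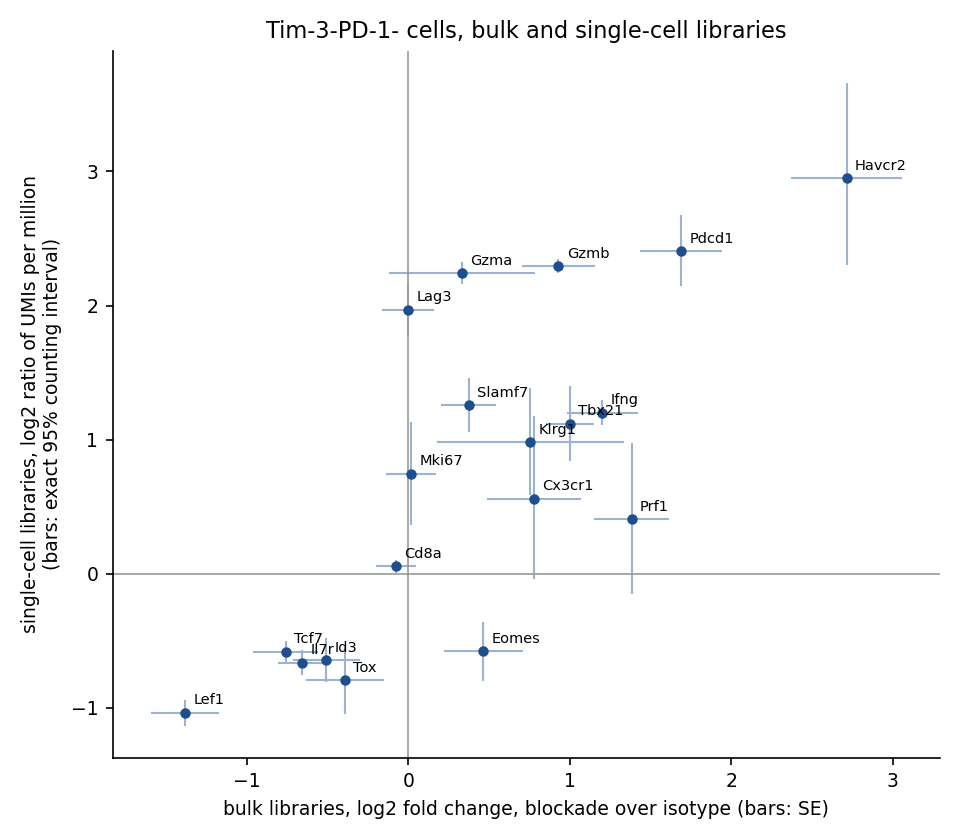
Log2 change under blockade of 19 genes in DN cells, with the bulk fold change and its SE on the x axis and the single-cell ratio with its exact 95% counting interval on the y axis. Havcr2 and Pdcd1 lay highest in both (bulk 2.72 and 1.69), and Eomes lay at 0.47 in bulk and -0.58 in single cells.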

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

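The tests that weigh an explanation in this part were chosen only after the result was seen; the test of the difference between the blockade effects was planned.

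Havcr2 and Pdcd1, the genes of Tim-3 and PD-1, rose under blockade in cells sorted as negative for both proteins. The antibodies of the blockade are directed to the same proteins, and whether the treatment altered the sort on them was not tested. Myeloid cells like those of the single-cell clusters are argued against as the source of most of the gain, since the top genes of these clusters rose too little in the bulk libraries. Taken as the upper quartile over the top genes, they could bring 3.41% of the gain of Havcr2 and 0.361% of that of Pdcd1 in the highest of the 3 blockade libraries. The highest single top gene gave 14.7% for Havcr2. These estimates carry ratios between genes from a few single cells over to bulk libraries. Of the Havcr2 UMIs in the single-cell blockade library, 14.1% [9.26 to 20.3] lay in the myeloid-like clusters, so a part from such cells is not excluded. Tim-3+PD-1+ cells in the Tim-3-PD-1- gate stay open: for 21 genes far more abundant in DP cells, the gain in DN cells made a median share of 4.12% of the DP level (quartiles 2.05 and 13.3%), and 3.37% (2.05 and 6.01%) without Lyz2, Thbs1, Adam8 and Il1r2, whose blockade UMIs lay mostly in the myeloid-like clusters, against 6.88% for Havcr2 (4.52 to 10.4% in single libraries) and 12.7% for Pdcd1. A transcriptional response of DN cells, the biological explanation that the treatment gives, also stays open. In these data the sort on both proteins could remove most DP cells without excluding a share of a few percent. DP cells of the mean profile would bring 1 common share to all of these genes, but the shares varied widely. Of the other 17 genes, 7 had a share at or above the lowest library share of Havcr2. Gzmf (0.899%), Gzme (0.947%) and Serpinb9b (1.08%) lay far below it, so such cells could bring only a part of the gain. How large a part is not known, and the explanations cannot be told apart.

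Erythrocyte transcripts were abundant in the isotype libraries of both populations and nearly absent after blockade, with Hba-a1, chosen after its values were seen, at 3015 ± 1115 CPM in DN isotype, 35.5 ± 56.1 in DN blockade, 1736 ± 819 in DP isotype and 7.02 ± 6.84 in DP blockade libraries. A difference in depth is argued against, since total counts of isotype libraries were 0.924 times those of blockade libraries. Red cells or their RNA in the isotype libraries stay open: ratios between erythrocyte genes varied between libraries with a median SD of 0.506 log2 units, against 0.691 for their levels. Fewer red cells in treated tumours cannot be told apart from handling with 1 single-cell library per treatment. There, 5.56% [4.76 to 6.45] of isotype and 7.67% [6.66 to 8.79] of blockade cells that passed the filter held a haemoglobin UMI, the opposite order to bulk. The size of this difference depends on the cell filter. The median log2 ratio of the blood list was 4.01 (percentile 100) after the filter and 0.40 (percentile 92.4) with all cells.

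Transcripts of plasmacytoid dendritic cells were present in libraries of DN cells and, in the subset experiment, higher in memory-like than in naive-like cells for 20 of 20 genes (median 2.47) and than in effector-like cells for 19 of 20 (median 2.85). Plasmacytoid dendritic cells in the Tim-3-PD-1- gate may be the source: a median of 44.2% of the UMIs of the list lay in 1 cluster of 36 cells (0.660% of cells), 1 of the clusters named myeloid-like, although the sort for CD8+ cells would remove those without CD8. Transcription of these genes by the CD8+ T cells cannot be told apart from this, because the T cell clusters of the isotype library lay at a median log2 ratio of -4.84 to bulk CPM, but the whole library, with that cluster, lay nearly as low at -4.24 (-0.98 for all genes), so it held too little of these RNAs to exclude a source. Of 20 genes of the list, which includes Ccr9 and Cd4 that T cells also express, 20 were lower in bulk DN cells under blockade (median -0.71) and 20 were lower in DP than DN cells under isotype (median -6.21). In single cells 13 of 19 were higher after blockade (median 0.37, against 0.16 over genes with at least 200 UMIs), 7 with an interval above 0 and 3 with an interval below 0. The cluster held 0.508% [0.285 to 0.837] of isotype and 0.839% [0.520 to 1.28] of blockade cells. These intervals overlap, so the fall in bulk was not seen in single cells, but an opposite order is not shown. Siglech had 0 UMIs in both single-cell libraries, although the table lists it, and the limit of 0.298 CPM holds only if its reads could be counted there, which is not known.

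Of 96 comparisons of memory-like and naive-like libraries with their own groups, 8 found a library far from the others. Chance gives about 5%, or 1 in 20. Effector-like and treatment libraries were not compared in this way. Effector-like replicate 3 had a median rank correlation of 0.900 with its own group and 0.907 with the other groups. Effector-like replicate 1 had 0.918 and 0.874, and replicate 2 had 0.919 and 0.870. Memory-like replicate 5 held 6527589 counts, and the nearest library of its group 5675135. Memory-like replicate 2 had a median rank correlation with its group of 0.878, and the nearest library 0.936. The myeloid score (mean log2 CPM) of memory-like replicate 2 was 4.29, and the nearest was 2.13. Its log2(CPM + 1) of Slamf7 was 4.92, and the nearest was 6.26. Naive-like replicate 6 had a G2/M score of 3.22, and the nearest was 1.3036. Its tumour and stroma score was 4.69, and the nearest was 1.03. Its core T cell score was 8.36, and the nearest was 8.64. Naive-like replicate 4 had a log2(CPM + 1) of Tbx21 of 7.33, and the nearest was 6.61.

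The effect of blockade differed between DP and DN cells for the effector set (camera adjusted p = 0.0291 with an estimated correlation, median difference -0.36) and for the naive set (adjusted p = 0.0299, median difference 0.65), as a test of the difference itself. With the SK number of the libraries as a block the adjusted p was 0.0753 for both sets, so the difference depends on a pairing that stays open.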

How the results depend on the processing

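The libraries left out for standing apart, Rn45s left out, the blocks by pools of name numbers and in DN libraries alone, and the SK block for sets were chosen after the result was seen; the other alternatives were planned. The 8 gene counts stayed within 1.5 times their value with DESeq2 size factors, a filter of 10 counts and Rn45s left out. DESeq2 called 539 genes for effector-like against memory-like, 1284 for effector-like against naive-like, 1318 for memory-like against naive-like, 521 for blockade in DN, 55 for blockade in DP and 98 for the difference of both. With no filter the last 3 were 224, 17 and 7. A threshold of 1 log2 unit gave 122, 469, 313 and 60.0 for the first 4 comparisons, and 1660.0 and 1400.0 for DP against DN under isotype and blockade. For blockade in DN, limma-trend on the authors' values gave 226 and voom 203, and for blockade in DP voom gave 1. Only the compared groups gave 2 in DN and 16 in DP. Without the memory-like and naive-like libraries that stood apart, effector-like against naive-like gave 1319. The cause was not tested.

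Leaving out 1 library gave 105 to 215 (effector-like against memory-like), 484 to 1068 (effector-like against naive-like), 340.0 to 815 (memory-like against naive-like), 22 to 229 (blockade in DN), 3 to 9 (blockade in DP), 0 to 3 (difference), 2880.0 to 4041 (DP against DN, isotype) and 2386 to 3143 (DP against DN, blockade). Subset sets without S phase and G2/M genes gave, with the preset correlation, 3 sets in DN, 0 in DP, 3 for the difference, 3 under isotype and 2 under blockade. With an estimated correlation, the whole memory set did not pass in camera in DN (adjusted p = 0.0867) or for the difference (adjusted p = 0.150).

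Blocks by numbers of the libraries were checked for pairing, and residuals correlated over 0.1 in 3 of 12 pairs by title number and 3 of 6 by SK number in the treatment experiment, and in the subset experiment in 0 of 11 by title number, 0 of 5 by name number between memory-like and naive-like and 3 of 6 between effector-like and memory-like libraries. By title number, the 3 over 0.1 were the 3 pairs of DN isotype with DN blockade libraries (0.122 to 0.383, other pairs at most 0.199). This match was found in the data alone, among 3 libraries per group whose SK numbers differ, so it does not establish pairing. Elsewhere not every pair correlated over 0.1, and pairing was not established either. It stays open by SK number (median 0.117, against -0.0741 for other pairs) and between effector-like and memory-like libraries (0.0826 against -0.0943), where 10 of 12 and 6 of 8 libraries correlated best with their own number. The title block gave 123 for effector-like against memory-like, 59 for blockade in DN, 4 for blockade in DP and 1 for the difference, and in DN libraries alone 529 for blockade in DN and 28 for the difference; the SK block gave 1, Hbb-b1, for the difference, and the name number block 174 for memory-like against naive-like. Pools of name numbers as a block gave 216 for effector-like against memory-like. With the SK block and an estimated correlation, 0 sets passed for the difference (adjusted p = 0.0753 for the effector and naive sets, 0.117 for the memory set), 2 under isotype and 2 under blockade. The cause was not tested.

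Lists called went from the preset to the estimated correlation from 10 to 6, 12 to 4, 15 to 7, 13 to 4 (DN), 11 to 1 (DP), 9 to 0 (difference), 16 to 5 and 15 to 5; fry called 4 in DN, 1 in DP and 0 for the difference. Of 193 single lists and sets, 71 no longer passed with an estimated correlation. In single cells, the log2 ratio of Cd8a went from 0.05 to -0.10 with median-of-ratios scaling, which shifts the ratio of each gene by the same amount, so this sign near 0 says nothing of the gene, and the tumour or stroma list moved from percentile 100 to 0.16 after thinning to 1000 UMIs. Leiden resolution 0.5 moved 7 and 1.5 moved 3 of 12 cluster shares beyond their intervals, and T cell clusters alone moved 11 of 47 values. Depth limits genes at a few CPM in bulk and widens the counting intervals of genes with few UMIs in single cells.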

Other observations

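The tests on splits of the libraries and the genes named outside the fixed lists in this part were chosen only after the result was seen.

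The interferon-response cluster held 64 isotype and 260.0 blockade cells, with Ifit1, Ifit3 and Isg15 among its top genes, and the list stood at a median log2 ratio of 1.58. Antigen presentation genes were higher in blockade cells for 19 of 19 members (median 0.53), glycolysis genes for 16 of 17 (0.79) and G2/M genes for 24 of 25 (0.82), against a median of 0.16 over all genes. Of the genes with the lowest ratios, Itgae, which encodes the integrin CD103, was at 20.3 and 2.98 CPM of UMIs (log2 -2.77 [-3.31 to -2.27]), Dapl1 at 387 and 63.5 (-2.61) and Izumo1r at 51.7 and 11.3 (-2.20). The residency list was higher in blockade cells for 10 of 12 members (median 0.64), so the fall of Itgae does not stand for residency genes. The genes with the highest ratios included Ccl8, Fst, Clec4d, Fcgr4 and the haemoglobin gene Hbb-bt. Each had UMIs in few blockade cells, from 0.679% for Ccl8, Fst and Hbb-bt to 1.60% for Fcgr4. Of the cells outside the T cell clusters, 28.8% held Fcgr4, 24.5% Clec4d, 11.5% Fst, 6.47% Ccl8 and 2.88% Hbb-bt. These genes were ranked after the cell filter, on which blood genes depend. The median log2 ratio of the blood list was 4.01 after the filter and 0.40 with all cells. Of the UMIs of Lyz2 and Fcgr1 in the blockade library, 94.9% and 95.5% lay in the myeloid-like clusters, and the myeloid list moved from percentile 100 to 42.2 when T cell clusters alone were used.

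A cluster with Klra7, Klra6, Klra1, Ikzf2 and Xcl1 among its top genes held 253 isotype cells (8.58% [7.59 to 9.65]) and 467 blockade cells (18.7% [17.2 to 20.2]). In bulk DN libraries the levels did not rise with this share: Klra7 was lower by 1.18 ± 0.34, Klra6 by 1.09 ± 0.44, Klra1 by 1.24 ± 0.55 and Ikzf2 by 0.50 ± 0.31 on the log2 scale under blockade. None of these passed in edgeR (adjusted p = 0.118 for Klra7). A share of cells is another measure than a bulk level, so an opposite order is not shown. In the subset experiment these genes set effector-like cells apart from both other subsets, with Klra7 at 17.4 ± 13.0 CPM in effector-like, 214 ± 38.9 in memory-like and 262 ± 47.5 in naive-like cells and Ikzf2 at 9.74 ± 3.26, 81.3 ± 11.8 and 107 ± 32.3. Xcl1 was at 4.62 ± 2.77, 81.5 ± 48.1 and 25.7 ± 11.9 CPM. Markers of tumour and stroma set 3 libraries of the subset experiment apart: the mean log2 CPM of the list was 4.59 and 4.65 in effector-like replicates 1 and 2 and 4.69 in naive-like replicate 6, against 0.27 in effector-like replicate 3, at most 2.61 in memory-like and at most 1.03 in the other naive-like libraries.

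If the libraries are independent, which is not known for the effector-like ones, splits of the libraries exclude chance at a share of 1 in 56 for effector-like against memory-like (237 genes, highest other split 13), 1 in 84 for effector-like against naive-like (795, highest other 326) and 1 in 100 for memory-like against naive-like (683, highest other 19). The split with 326 genes set effector-like replicates 1 and 2 and naive-like replicate 6 against the rest, the libraries with the highest tumour and stroma scores, which points to a structure of the samples. For groups of 3 libraries the 10 splits are too few for a share under 0.05; the real and the highest other counts were 142 and 1 for blockade in DN, 8 and 0 for blockade in DP, 3794 and 0 for DP against DN under isotype, and 3426 and 1 under blockade. For the difference of the blockade effects, the real count was 0, which each of the 100 splits reaches, so they say nothing about chance. The split with the highest count, 72, exchanged isotype and blockade in all DN libraries and kept them in DP, so its structure is that of the treatments: it adds the effects of blockade in DN and DP instead of taking their difference.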
